A study of Caenorhabditis elegans with 2 samples.

How the data were processed

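The samples were 2 biological replicates of 1 group: whole Caenorhabditis elegans L4 larvae, 48 hours old, grown from starved first-stage larvae and carrying an integrated transgene that expresses the protein of Y105C5A.15 fused to EGFP with TY1 and FLAG tags. The same transgene carries a rescuing copy of unc-119. Per the labels, chromatin was sheared by sonication and precipitated with an antibody against GFP, and the sequenced fragments were placed on assembly ce11. The group and the replicate number of each sample come from its description. The labels give no second condition, so the design implies a map of binding sites and a comparison of replicate 1 with replicate 2. An input or untagged sample was not analysed here as a sample of its own.

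The deposited files are peak lists. Per the labels' text records, a list was made for each replicate and for both replicates together, from filtered alignments and 1 control alignment file. The peak caller, the aligner and their versions are not given in the sources used here. For each set there was a ranked list of all peaks and a thresholded list. The irreproducible discovery rate (IDR) is the expected share of peaks whose rank does not repeat between replicates or pseudoreplicates. The ranked lists hold the −log10 of the global IDR that the authors computed for each peak. The signal of a peak is the authors' value from their peak caller, and its scaling is not given in the sources used here. The score is a whole number of up to 1000 that the deposited lists derive from the IDR. Each thresholded list held peaks of its ranked list with an IDR of at most 0.01. Not every ranked peak past that limit was kept, and the text records name 1 further input for the thresholded lists, whose role they do not give. The longer thresholded list over both replicates is the main list, and the conservative list of the authors, which is not a subset of it, is an alternative. The lists carry no read counts, so the sequencing depth is unknown, and intervals below cover counting error of regions only.

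Overlapping intervals of a list were merged into regions, and the summit and signal of the strongest peak were kept. Chromosome lengths of the WBcel235 assembly, which is ce11, covered all peak ends. Coordinates are 1-based. Genes came from the Ensembl annotation of release 115, with 610 names of small RNA genes added from a RefSeq table by identical position. The mitochondrial genome was left out. The promoter window reached from 1000 bases upstream to 200 bases downstream of a gene start. A region was placed at a small RNA gene when its summit lay within 100 bases of an annotated tRNA, snoRNA, snRNA or rRNA gene.

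The overlap of the replicates and the positions of summits were tested with 1000 random circular shifts of the regions along each chromosome, one-sided for the overlap and two-sided for positions. The smallest p these permutations can give is 0.001. The signal of each main region in a replicate was the signal of the strongest overlapping peak in that replicate's own ranked list. Pearson and Spearman correlations of log2 signal were computed across regions, which are not independent replicates, with 100000 permutations. Chromosome shares were compared with chromosome length by two-sided exact binomial tests. The 42 gene lists, fixed before the data were examined, were tested by two-sided Fisher's exact tests, coding lists against all other protein-coding genes and RNA lists against all other non-coding genes. Lists with fewer than 5 annotated members were not to be tested. Words of 6 bases were counted on either strand in 100-base windows on the summits and in windows centred 300 bases to each side. Words found on chromosomes I, III and V were tested on II, IV and X, with two-sided Fisher's exact tests. The difference in median signal between regions inside and outside promoter windows was tested with 100000 two-sided permutations, for which the smallest p is 1e-05. Families of tests were adjusted by the Benjamini-Hochberg method at 0.05. Shares have 95% exact Clopper-Pearson intervals.

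The genes named were set by rule before the data were examined: the 25 main regions with the highest signal, each named after the annotated gene with the nearest start within 2000 bases, the targeted gene and unc-119, and the 4 members with the highest signal of each gene list past the threshold. The list test was tested on simulated data: over 50 simulated sets of 1023 regions and 42 lists, 100.0% of the planted lists and 0.8% of the other lists were called. Planted summits lay exactly at gene starts, more per list than any coding list past the threshold had. The remaining regions were shifted ones, which lack the preference for gene starts. These rates therefore do not cover weaker excesses or that preference. The word test called a planted word, and with none planted it called 0 of 2080 words. Its sites were random, so this check does not cover the difference in GC content between real summits and flanks. Alternatives covered the conservative list, the upper 50% of regions by signal, each replicate alone, other windows, other overlap rules, other word lengths and backgrounds, shifts in place of Fisher's exact test, and assignment to the nearest start only. Analysis with the small RNA genes left aside, the background of matched GC content, and signal by position in each replicate alone were chosen after seeing the data. Peaks with a second copy in the genome were found by blastn 2.17.0 as alignments of at least 100 bases and 90% identity with the 200 bases around the summit. For tRNA genes a near-identical copy was an alignment of the gene over at least 50 bases at 90% identity, and genes within 500 bases of a copied tRNA gene were left out. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.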

Results

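Chromatin immunoprecipitation of the tagged Y105C5A.15 protein and sequencing were done in L4 larvae, in 2 biological replicates of 1 group. No sample here lacked the tagged protein. At any region, antibody signal without that protein therefore cannot be told apart from binding. The main list of the authors held 1046 peaks, which merged into 1023 regions with a median peak width of 256 bases. The conservative list gave 831 regions, and the lists of replicate 1 and replicate 2 alone gave 349 and 323. The authors' signal had a median of 63.5 over the main peaks, with quartiles at 55.3 and 81.4. All coordinates are on ce11. The depth of the libraries is unknown, since the lists hold no read counts.

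Many regions lay at small structural RNA genes. Of the 1023 main regions, 310 (30.3%, 95% interval 27.5 to 33.2%) had their summit within 100 bases of such a gene, against a mean of 3.48 under shifts (permutation p = 0.001, the smallest 1000 shifts can give). Regions at tRNA genes, which make the adaptors of translation, were 23.6% of all regions, 54 regions lay at snoRNA genes, whose RNAs guide RNA modification, and 15 at snRNA genes. No region of the list lay at an rRNA gene (95% interval up to 0.36%), though 1 ranked peak past the IDR limit that the list lacks did (signal 62.95). Median signal was 102 at snoRNA genes, 76.0 at tRNA genes and 60.3 at the 713 other regions. The share at small RNA genes was 41.3% in replicate 1 alone and 45.5% in replicate 2 alone.

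The region with the highest signal lay 30 bases upstream of the snoRNA gene ZK994.7 (V, 8500481 to 8500650, in an intron of a coding gene), with a signal of 296. Its signal was 136 in replicate 1 and 160 in replicate 2 (mean 148 ± 17.3 SD, n = 2). T03F7.8 (V, 11314188 to 11314260; also intronic) followed with 236 and a replicate mean of 118 ± 1.08 (SD, n = 2). The snoRNA genes C51F7.4, W03C9.9, ZK265.10, F32E10.10 and T19B4.8 were also among the 25 strongest regions, with signals of 229, 209, 178, 151 and 148. The tRNA genes M02F4.t1 (X, 3036013 to 3036268, intergenic, signal 175), C04A11.t1 (155), ZK563.t1 (153), R01H5.t1 (152) and C33G3.t2 (150) were there as well, with summits no more than 23 bases from the gene start. The tRNA gene W02H3.t1 was the nearest to a region 1451 bases away (151).

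Among coding genes, the strongest region was 152 bases upstream of F44E5.4, an Hsp70-family chaperone gene (II, 11759335 to 11759590, intergenic, signal 233, replicate mean 118 ± 22.03 SD, n = 2). The ribosomal protein gene rpl-3 had a region 273 bases upstream (III, 3867519 to 3867596, intergenic, signal 184, replicate mean 95.2 ± 4.46 SD, n = 2). The other coding genes named by the 25 strongest regions were R11A5.6 (185), mdt-26 (169), C14C11.7 (164), vps-37 (162) and tasp-1 (151). The summits lay 608 bases upstream of vps-37 and 62 bases upstream of tasp-1. Those of R11A5.6 (1198 bases upstream), C14C11.7 (1452 bases upstream) and mdt-26 (564 bases downstream, in a coding exon) lay outside that gene's promoter window. The RNA gene of RNase P, rpr-1, had a summit 16 bases into the gene (I, 13463843 to 13464098, signal 171, replicate mean 82.8 ± 43.6 SD, n = 2). The other non-coding neighbours were the ncRNA gene K02F3.13 (181) and the piRNA gene 21ur-15381 (216). The 2 remaining regions, on I (173) and X (166), had no gene start within 2000 bases. Of the 25 regions, 7 had a near-identical second copy of their sequence elsewhere in the genome, among them those of 21ur-15381, R11A5.6, C04A11.t1, ZK563.t1 and C33G3.t2.

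**Figure D1:**
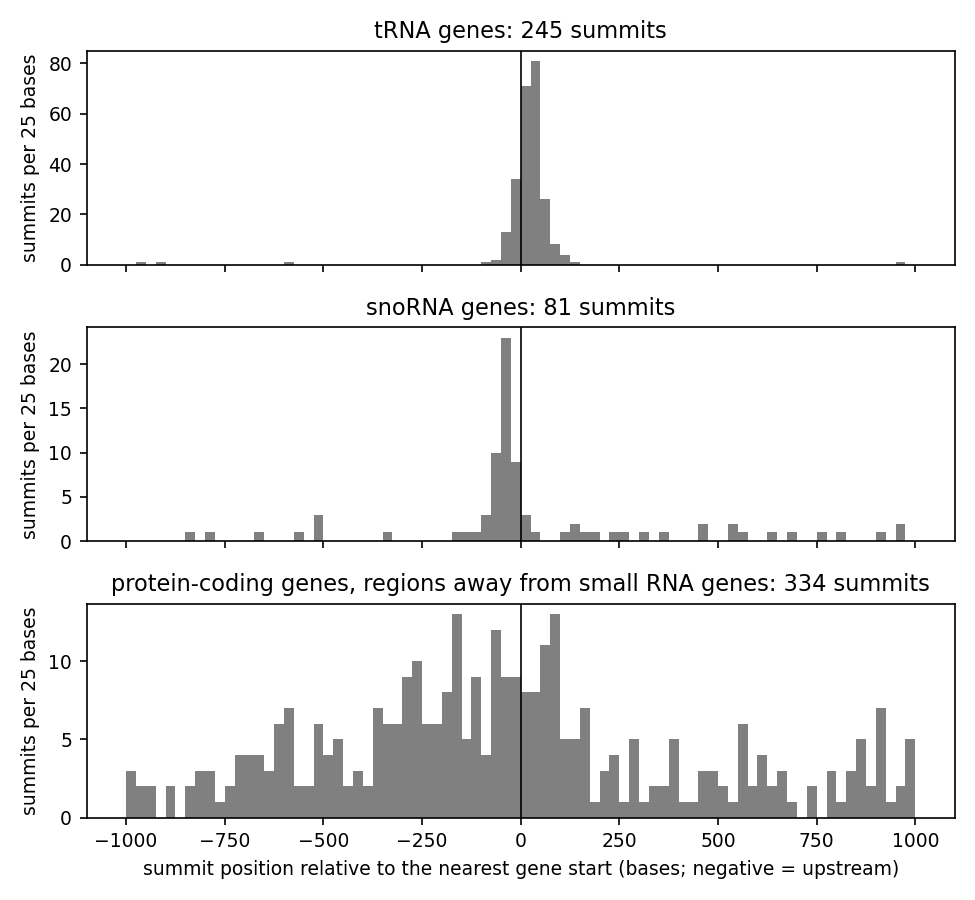
Number of summits per 25 bases against the distance to the nearest gene start in bases, negative upstream, for tRNA genes, snoRNA genes and protein-coding genes (the last for regions away from small RNA genes). The 245 summits near tRNA starts had a median position of 24 bases downstream, and the 81 near snoRNA starts a median of −35.

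Replicate 1 and replicate 2 were compared to ask how far the regions repeat. Of the 349 regions of replicate 1, 171 (48.997%, 95% interval 43.6 to 54.4%) overlapped a region of replicate 2, against a mean of 0.58 under shifts (one-sided permutation p = 0.001). In the other direction 171 of 323 regions were shared (52.9%). The main list took up 323 of the regions of replicate 1 and 307 of those of replicate 2, while 459 of the 1023 main regions (44.9%) overlapped a region of either replicate alone. Of the 831 conservative regions, 723 overlapped a main region. Over 997 main regions with a ranked peak in both replicates, log2 signal correlated with Pearson's r = 0.43 and Spearman's rho = 0.34 across regions (each permutation p = 1e-05, adjusted p = 1.67e-05 for r and 1.25e-05 for rho over 5 sets of regions). At snoRNA genes r was 0.62 over 53 regions (permutation p = 2e-05, adjusted p = 2.5e-05), at tRNA genes 0.37 over 233 and at other regions 0.34 over 697 (both permutation p = 1e-05, adjusted p = 1.67e-05). Spearman's rho was 0.646 at snoRNA genes, 0.370 at tRNA genes and 0.182 at other regions (each permutation p = 1e-05, adjusted p = 1.25e-05). At the 14 snRNA regions neither r (0.50, permutation p = 0.0668) nor rho (0.275, permutation p = 0.343) passed. These are correlations over regions chosen by an IDR limit, which can compare replicates or pseudoreplicates.

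**Figure D2:**
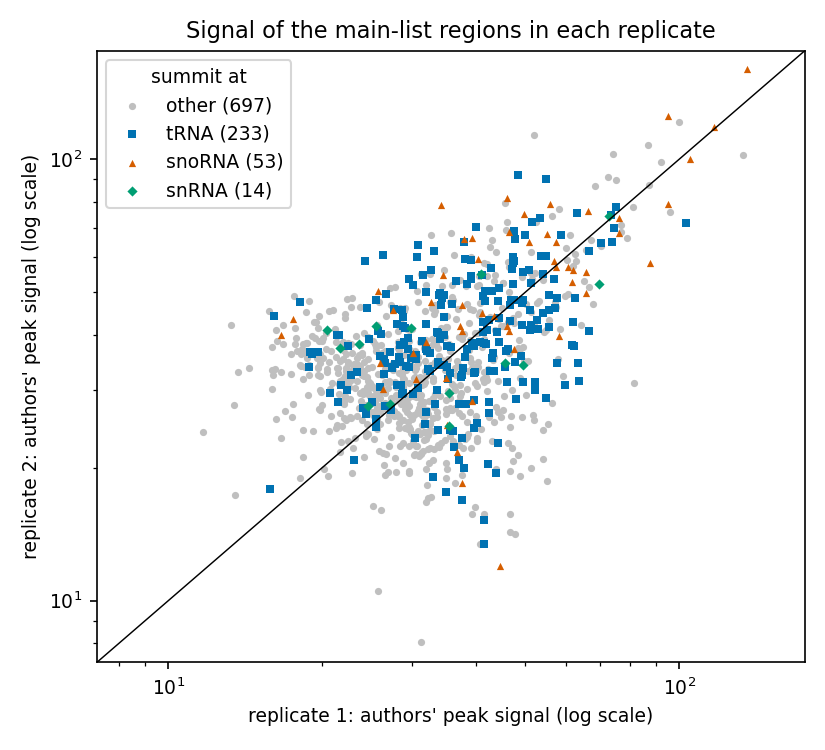
Authors' peak signal of each main region in replicate 2 against replicate 1, both on log axes, with the line of equal signal; symbols mark regions at tRNA, snoRNA or snRNA genes and all others. The 997 regions with a value in both replicates are drawn.

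Regions lay at gene starts more often than shifted regions did. In promoter windows of any gene lay 654 of 1023 summits (63.9%, 95% interval 60.9 to 66.9%), against 33.9% under shifts, and in those of protein-coding genes 339 (33.1%) against 20.99% (each permutation p = 0.001, adjusted p = 0.0016 over 8 positions). Exons of non-coding genes and pseudogenes held 25.3% of summits against 2.92%, while coding exons held 13.4% against 24.5% and introns 18.4% against 34.9% (each permutation p = 0.001, adjusted p = 0.0016). The 5′ UTR (2.35% against 1.41%, permutation p = 0.022, adjusted p = 0.0251) and the 3′ UTR (5.28% against 3.39%, permutation p = 0.004, adjusted p = 0.00533) held more summits than shifted regions. Intergenic sequence held 35.3% against 32.9% (permutation p = 0.13). With regions at small RNA genes left aside, the share in promoter windows was 48.4% against 33.8% (permutation p = 0.001).

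Gene lists past the threshold were led by small RNA genes and ribosomal protein genes. A summit lay in the promoter window of 292 of 612 tRNA genes (47.7%, 95% interval 43.7 to 51.8%), against 2.06% of other non-coding genes (Fisher's exact test, adjusted p = 6.94e-283). For snoRNA genes it was 68 of 346 (19.7%, exact adjusted p = 8.35e-33) and for snRNA genes 16 of 129 (12.4%, exact adjusted p = 3.74e-05), a call lost in replicate 1 alone (6 genes, exact adjusted p = 0.0582) and in replicate 2 alone (6 genes, exact adjusted p = 0.0532). Some genes shared a region: counting each gene's strongest, the 292 tRNA genes rested on 236 regions, the 68 snoRNA genes on 65 and the 16 snRNA genes on 14. Fisher's exact test and the intervals treat genes as independent, which these are not. The other non-coding genes set against the RNA lists were of all kinds except pseudogenes, piRNA genes included, so their percent depends on that mix. Of the ribosomal protein genes, 11 of 79 (13.9%, 95% interval 7.16 to 23.5%) had a summit, against 1.89% of other coding genes (exact adjusted p = 4.88e-06). Chemoreceptor GPCR genes, which code for sensory receptors, had fewer by this test, 6 of 1308 (0.459% against 2.04%, 26.7 expected, exact adjusted p = 4.75e-05). Under circular shifts they were not past the threshold (11.66 expected, permutation adjusted p = 0.275). Shifted regions keep their clustering and their number on each chromosome but lose the preference for gene starts. The tests therefore differ in what they expect.

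The 4 ribosomal protein genes with the highest signal were rpl-3 (184), rpl-15 (146), rpl-35 (126.1) and rps-19 (112.1), all with the summit 273 to 457 bases upstream of the start. Among tRNA genes these were M02F4.t1 and M02F4.t2, a divergent pair that shares 1 region (175), C04A11.t1 (155) and ZK994.t2, whose window holds the summit at the snoRNA gene ZK994.7. The snoRNA genes were ZK994.7, T03F7.8, C51F7.3 and C51F7.4, the last 2 sharing a region. The snRNA genes were sls-2.8 (95.7), sls-2.1 (81.3), both genes of spliced leader RNAs, and 2 genes named R07E5.16 on chromosome III (133 at WBGene00014543 and 87.6 at WBGene00014484).

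Histone genes had summits at 8 of 81 (9.88%, exact adjusted p = 0.00121), led by his-37 (70.3), his-46 (67.2, WBGene00001930), his-59 (63.6) and his-63 (63.5). Of oxidative phosphorylation genes, which code for the respiratory chain, 7 of 71 had one (9.86%, exact adjusted p = 0.00267), led by cox-5A (123.2), cox-5B (98.5), nduf-2.2 (90.9) and nduf-9 (79.8). The chaperone genes hsp-60 (99.2), hsp-6 (71.2) and hsp-1 (63.8) were the 3 of 22 heat shock genes with a summit, and mog-4 (104.02), prp-19 (98.2), rsp-6 (64.3) and snrp-200 (63.3) led 5 of 66 spliceosome genes (both exact adjusted p = 0.0422). The Hsp70-family gene F44E5.4, with a summit 152 bases upstream of its start (233), was not a member of the heat shock list. Among chemoreceptor genes sre-23 (178), srh-269 (82.7), srw-95 (67.4) and sri-5 (58.9) had the highest signal, and the summits near sre-23 and srh-269 lay within 100 bases of a small RNA gene. The other 33 of the 42 lists did not pass, among them chromatin regulators (6 of 99, exact adjusted p = 0.053), translation factors (3 of 45, exact adjusted p = 0.202) and miRNA genes (7 of 261, exact adjusted p = 1). Chromatin regulators passed with circular shifts (permutation adjusted p = 0.018), in replicate 1 alone (exact adjusted p = 0.0296) and away from small RNA genes (exact adjusted p = 0.0236). Genes of the unfolded protein response and secretion (4 of 75, exact adjusted p = 0.202) passed with circular shifts (permutation adjusted p = 0.042) and in replicate 2 alone (4 genes, exact adjusted p = 0.00998). Shifted regions lack the preference for gene starts, so calls gained with shifts differ in kind from those of Fisher's exact test. The miRNA genes passed away from small RNA genes (exact adjusted p = 0.015), but their count stayed at 7. Small RNA genes stayed in the background without their regions, so only the expected number fell, by construction. The chemoreceptor call was also lost in replicate 1 alone (exact adjusted p = 0.0582), and the calls of histones (exact adjusted p = 0.592), oxidative phosphorylation (0.0759), heat shock (0.151) and spliceosome genes (0.215) were lost with a window of 500 bases upstream to 100 bases downstream. The heat shock call was also lost with the conservative list (exact adjusted p = 0.16), in the upper 50% by signal, in each replicate alone and with the nearest start only. The spliceosome call was also lost in the upper 50% by signal, in replicate 1 alone (exact adjusted p = 0.744), with the nearest start only and away from small RNA genes. The histone call was also lost in the upper 50% by signal and in replicate 2 alone, and that of oxidative phosphorylation with the nearest start only. Of the 8 histone regions, 4 had a near-identical second copy in the genome, as had 11 of the 14 regions behind the snRNA list. So had 88 of 236 behind the tRNA list, 2 of 5 spliceosome regions and 2 of 6 chemoreceptor regions, against 20.1% of regions away from small RNA genes. Lower shares were found for snoRNA (7 of 65), ribosomal protein (1 of 11), oxidative phosphorylation (1 of 7) and heat shock regions (0 of 3).

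**Figure D3:**
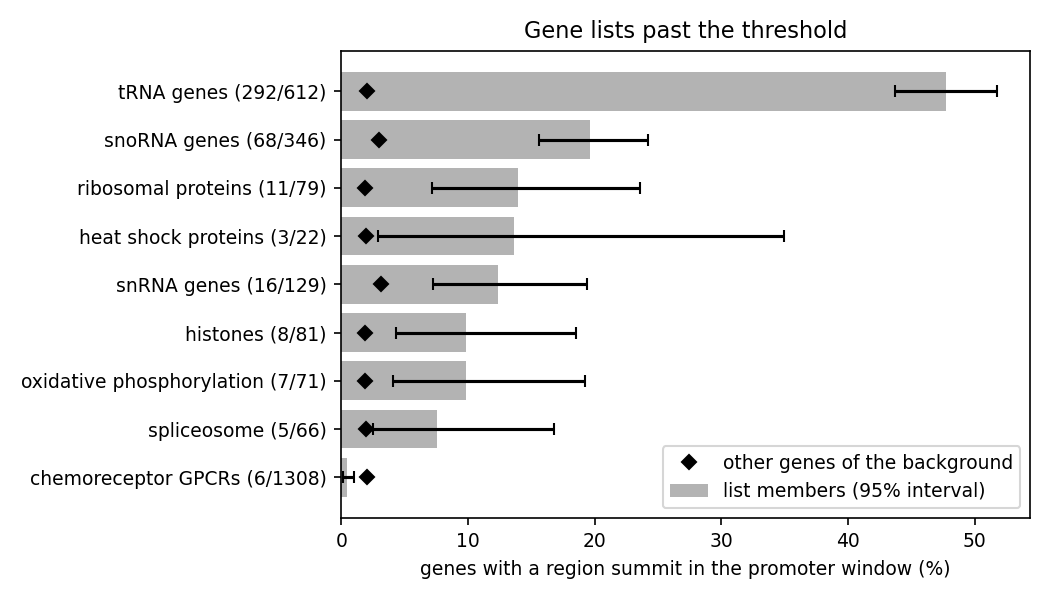
Percent of the genes of each list past the threshold that had a summit in the promoter window, as bars with 95% exact intervals, and of the other genes of its background, as diamonds. The tRNA genes reached 47.7% and the chemoreceptor genes 0.459%, a call that circular shifts did not give.

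Chromosome III carried more regions than its length share and chromosome V fewer. Chromosome III had 194 regions against 141 by length (1.38 times, exact binomial adjusted p = 1.03e-05) and V had 130 against 213 (0.609 times, exact binomial adjusted p = 8.01e-11). Chromosome I had 1.16 times (exact binomial adjusted p = 0.0575) and X 1.07 times (exact binomial adjusted p = 0.488). X carries 276 of the 612 tRNA genes. Among the 713 regions away from small RNA genes, X had 76 against 125.99 (0.603 times, exact binomial adjusted p = 4.54e-07) and I had 139 against 107.2 (1.297 times, exact binomial adjusted p = 0.00204), a comparison chosen after the data were seen. The excess on III was not past the threshold in replicate 1 alone (1.21 times, exact binomial adjusted p = 0.18), replicate 2 alone (1.104 times, exact binomial adjusted p = 0.56) or the upper 50% by signal (1.25 times, exact binomial adjusted p = 0.0576).

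**Figure D4:**
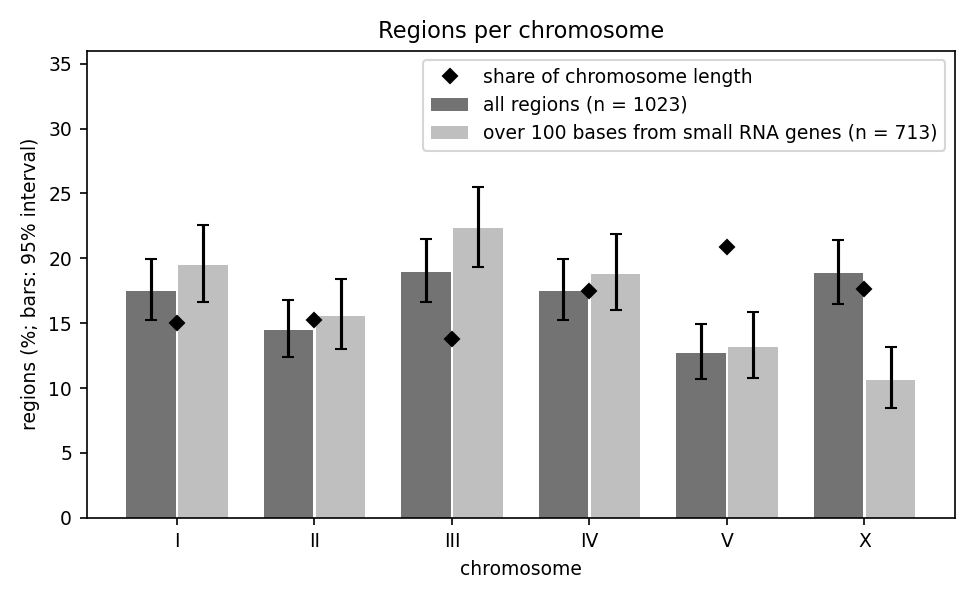
Percent of regions on each chromosome, for all 1023 main regions and for the 713 over 100 bases from small RNA genes, with 95% exact intervals, beside the chromosome's share of length as diamonds. X held 18.9% of all regions and 10.7% of those away from small RNA genes.

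Summit windows held certain short words more often than flanking windows did, led by CGAACC. On chromosomes II, IV and X, the word CGAACC lay in 102 of 520 summit windows (19.6%) against 3.08% of flanking windows (Fisher's exact test, adjusted p = 7e-24), GAACCC in 16.5% against 2.12% (exact adjusted p = 1.47e-22), ACCACT in 19.6% against 3.46% (exact adjusted p = 1.47e-22) and GTTCGA in 20.6% against 4.81% (exact adjusted p = 4.95e-19). GTTCGA and CGAACC belong to the internal B box of tRNA genes as background knowledge. Of 287 words found on I, III and V, 230 passed on the other chromosomes. The split does not keep copies apart: 469 of the 612 tRNA genes have identical copies, so both parts can hold the same sequence. Passing on II, IV and X is therefore not a fully independent test, and Fisher's exact test treats such windows as independent. Summit windows had a median GC content of 48%, against 35% in the flanks, and against random windows of the same GC content 29 words passed. With regions at small RNA genes left aside, 61 words passed against the flanks by Fisher's exact test. The lowest p was that of GGCCGA (8.10% against 1.09%, exact adjusted p = 7.5e-06). ACCACT also passed (7.48% against 2.96%, exact adjusted p = 0.0078). CGAACC, GAACCC and GTTCGA were not among the words found on I, III and V in this setting. Against windows of matched GC content 0 passed. There, 85 of 2080 words were more frequent in summit windows with an unadjusted p under 0.05 by Fisher's exact test on I, III and V. The number that chance alone would give was not estimated, so no excess or lack is read from this count.

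Regions in promoter windows had a higher signal than the others. The median was 67.3 over 654 regions inside and 59.9 over 369 outside, a difference of 7.42 (two-sided permutation p = 1e-05). The difference was 0.976 with regions at small RNA genes left aside (permutation p = 0.299), 1.77 in replicate 2 alone (permutation p = 0.415) and 4.003 in replicate 1 alone (permutation p = 0.00272). Signals run lower in each replicate's own list (median 46.6 in replicate 1 and 49.2 in replicate 2, against 63.5 in the main list). The size of a difference in 1 replicate therefore cannot be set directly against 7.42.

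The targeted gene itself had no region. Y105C5A.15 (WBGene00013639, IV, 15689201 to 15722553) had 0 regions in the main, conservative and replicate lists, from 1000 bases upstream of its start to 200 bases past its end. Its strongest ranked peak, 360 bases upstream of the start, had a signal of 39.4 and an IDR of 0.278. At unc-119 (WBGene00006843, III, 10902641 to 10908935), the marker gene of the transgene, there were also 0 regions, and the strongest ranked peak had a signal of 32.6 and an IDR of 0.496. These loci therefore offered no check of the labels.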

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

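The tests of neighbouring gene starts at tRNA genes, of summits at tRNA genes without copies, of the antibody's signal and of chromosome X were chosen only after the result was seen. Ranked peaks that the thresholded lists lack stood out because no comparison above uses them. The main list lacks 135 ranked peaks that pass its IDR limit, and the strongest of them has a signal of 2922, on X from 15810952 to 15811193, against a highest signal of 296 in the main list. The 135 peaks fall into 63 places when joined within 10000 bases, and 18 of them (13.3%) lie in promoter windows. Of the 20 strongest ranked peaks past that limit, 19 are among them.

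Removal by place, with the same places in every list, was tested by overlap: 0 of the 2573 thresholded peaks of the 4 lists overlapped a missing peak of any list. A second, near-identical copy was found for 131 of the 135 missing peaks (97.04%, 95% interval 92.6 to 99.2%), against 249 of 1046 main peaks (23.8%). A candidate explanation is therefore that peaks in repeated sequence were removed by place before deposit. No biological explanation was tested.

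Regions at tRNA genes could come from coding gene starts close by, but of the 244 summits in tRNA windows 98.8% (95% interval 96.4 to 99.7%) lay within 100 bases of the tRNA gene, which argues against that. Reads shared between identical copies are argued against as the whole of it, since 24.4% of the tRNA genes whose sequence occurs once, away from copied tRNA genes, had a summit (29 genes, 95% interval 16.97 to 33.1%), against at most 2.52% under shifts. Sharing stays open for the rest: genes whose sequence occurs once had a summit 0.542 times as often as those with identical copies (95% interval 0.402 to 0.73, which reaches below the bound of 0.5 set against sharing), and of the only 10 such genes without even a near-identical copy or one close by, 0 had one (95% interval up to 30.8%), as sharing between near-identical copies would give. Signal the antibody gives without the tagged protein cannot be told apart from binding, since 0 samples here lack the tagged protein or carry another one. No biological explanation was tested.

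Away from small RNA genes, fewer regions lay on X. Fewer coding gene starts on X do not account for all of it, since 10.7% of the 713 regions lay there against 13.7% of coding gene starts (exact binomial p = 0.0189, unadjusted). Fewer peaks on X among all ranked peaks is argued against too, because 16.8% of them lay on X, above the 95% interval of the share of regions (8.49 to 13.2%). Most ranked peaks are weak (median signal 18.2, against 63.5 in the main list), so this speaks mainly for weak peaks and not for strong ones. Technical explanations such as the sequence content of X were not tested, and no biological explanation was tested, so the pattern stays a hypothesis.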

How the results depend on the processing

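The settings without small RNA genes, with matched GC content, and for signal by position in each replicate alone were chosen after seeing the data. Of 53 values under alternatives, 36 stayed on the same side of the threshold in the same direction, or within 1.5 times for counts. The cause was not tested unless named. The replicate overlap, the correlation of signal, the position of summits and the absence of regions at the targeted gene were among them under all alternatives run for them.

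The upper 50% by signal held 512 regions by construction, and the separate lists of 1 replicate alone 323 to 349. Gene lists past the threshold numbered 9 and fell to 5 with the narrow window, and to 6 or 7 in 1 replicate alone, of which 5 or 6 were shared. Chromosomes past the threshold numbered 2, 1 in each replicate alone, and 4 without small RNA genes. Words past the threshold numbered 230, and 142 in the upper 50% by signal, 40 to 73 in 1 replicate alone, 142 at 7 bases, 40 at 8 bases, 61 without small RNA genes, 29 with matched GC content and 0 with both. The signal difference of 7.42 became 0.976 without small RNA genes. In 1 replicate alone it was 1.77 to 4.003, with the lower value no longer past the threshold. Signals of those lists run lower and their regions differ, so the sizes are not directly comparable.

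The next counts cover the chromosomes and only those single lists that passed the threshold in at least 1 setting. Of these 138 values, 98 stayed the same in direction and side of the threshold, 22 lost the call, 7 gained it and 11 changed direction. Heat shock genes had 0 members with a summit without replicate 1, and genes of the unfolded protein response had 1 with the nearest start only. The miRNA genes, at 7 against 8.32 expected in the main list, lay above expectation with the wide window (13), circular shifts (7) and the nearest start only (6), none past the threshold, and without small RNA genes (7 against 1.72, past it). In that last setting only the expectation fell, because small RNA genes stayed in the background without their regions. Without small RNA genes the tRNA list had 2 and the snRNA list 0 by construction, chromosome II was at 1.02 times its length share and X at 0.603 times, of which only X passed the threshold. Chromosome IV was at 0.966 times with the conservative list, not past the threshold. In the upper 50% by signal X passed the threshold at 1.34 times and III no longer did at 1.25 times. Depth is unknown, so its effect on the number of regions could not be examined.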

Other observations

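Every test in this part was chosen after the data were seen. Counting summits within 100 bases of the gene, tRNA genes of most amino acids had regions. Apart from 1 selenocysteine gene and 5 genes without a named amino acid, which had 0, the share ran from 61.5% of 13 genes for cysteine and 55.6% of 27 for aspartate to 25% of 20 for methionine and 21.4% of 14 for phenylalanine. No amino acid differed from the rest past the threshold (Fisher's exact test, lowest adjusted p = 0.552). The share was 43.5% of the 276 tRNA genes on X and 39.9% of the 336 on the autosomes, with 95% intervals of 37.5 to 49.6% and 34.6 to 45.3%.

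Of snoRNA genes outside coding genes, 25 of 130 (19.2%) had a summit within 100 bases, against 23 of 183 (12.6%) inside a coding gene on its strand and 7 of 33 (21.2%) inside one on the other strand. None of these shares differed from the remaining snoRNA genes past the threshold (Fisher's exact test, lowest adjusted p = 0.236).

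The main list holds 17 peaks with a signal below the median of all ranked peaks (18.2), down to 2.06. Of these, 2 lie within 500 bases of a ranked peak stronger than the median main peak.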
